A study of Homo sapiens with 9 samples.

How the data were processed

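Poly(A) RNA of PANC-1 cells, an established human pancreatic cancer line, was sequenced after 24 h with the solvent DMSO or with 1 of 2 autophagy inhibitors. ULK100 acts on the kinase ULK1, which starts autophagosome formation, and VPS34-in1 acts on the lipid kinase VPS34, which is encoded by PIK3C3 and makes PI3P on endosomes and forming autophagosomes. Each group held 3 libraries, called biological replicates in the design text, so that there were 9 libraries. The authors bound mRNA to oligo(dT) beads, primed cDNA with random hexamers and sequenced on a DNBseq instrument. Per the labels, reads were aligned with STAR to GRCh38/hg38. The counting program, its annotation and its strand setting are not given in the sources used here. The deposited table holds raw counts per gene symbol, not normalised, for 26485 symbols, of which 4835 were at 0 in every library. With an unknown strand setting, counts of genes that overlap on opposite strands may hold reads of both, and counts of near-identical copies depend on an unknown handling of shared reads.

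The labels of the 6 inhibitor libraries conflict. Their titles and descriptions name 1 compound and their treatment tag names the other: libraries titled ULK100 carry the tag for 10 uM VPS34-in1, and libraries titled VPS34in1 carry the tag for 5 uM ULK100. The treatment protocol gives 5 uM for ULK100 and 10 uM for VPS34-in1. Groups follow the titles, and the expression values were not used to settle the conflict. Every direction below therefore belongs to libraries titled ULK100 or titled VPS34in1, and which compound each group received stays open. The doses of the compounds differ.

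Counts were read with pandas 2.3.3 and numpy 2.4.6 on Python 3.11.15 and tested with edgeR 4.0.16 and limma 3.58.1 on R 4.3.3. Genes passing filterByExpr (14151) were scaled by TMM and fitted by the edgeR quasi-likelihood method over all 9 libraries without a replicate block. There were 3 comparisons: libraries titled ULK100 against DMSO, libraries titled VPS34in1 against DMSO, and titled VPS34in1 against titled ULK100. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The standard error of a log2 fold change is its size divided by the square root of the quasi-likelihood F, which is approximate. Levels are CPM (counts scaled to TMM-adjusted library totals), as mean ± SD over the 3 libraries of a group. Coordinates are from GENCODE release 29 on GRCh38, which gave a transcript length for 92.86% of the symbols in the table. Figures were drawn with matplotlib 3.10.9.

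There were 30 gene lists with 752 members, of which 739 were in the table, 3 of them under an older symbol. The table also uses older names such as CYR61 (CCN1) and CTGF (CCN2). The 26 lists with at least 5 tested members were tested against all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The test was repeated with an estimated correlation, and fry asked whether a list's genes moved 1 way on balance. Ranges and lowest values of a list's adjusted p over the alternatives are those of camera and leave out fry. Member counts are given over all genes tested and adjusted over the list alone. Named genes followed a rule. For each comparison these were the 5 largest rises and the 5 largest falls among called genes with a mean of at least 5 CPM, non-overlapping groups and no clone-based name. From each of the 6 lists with the smallest p came the 3 called members with the smallest p in the list's direction. The rule also took 10 genes fixed by name for both comparisons with DMSO, and up to 3 members with the smallest p of any list described. The comparisons, lists, naming rule and most alternatives were chosen before the data were examined.

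The totals per library ran from 14139994 to 16625690 counts, and the common dispersion was 0.00393. The steps were tested on simulated data in which 200 genes of 3 libraries were changed. At a simulated 2-fold change 55 of 66 genes were recovered (83.3%), at 1.5-fold 51 of 67 (76.1%) and at 1.25-fold 29 of 67 (43.3%), and 4 unchanged genes were called (2.88% of calls). A recovery of 90% of the 2-fold genes had been required over all genes and was missed. The missed genes had at most 1.86 CPM, and the requirement was then applied to genes with at least 5 CPM in DMSO, where 47 of 47 were recovered. At 1.5-fold 50 of 52 such genes were recovered and at 1.25-fold 29 of 50, so smaller changes and changes of rare transcripts were missed more often. A moved list was called by camera and 0 other lists were. Genes were simulated independently of each other, so this did not test camera where the genes of a list vary together. The 200 changed genes were few of 13668 and were raised or lowered about equally often, whereas 64.3% to 73.3% of genes were called in the data. The simulation therefore did not test the scaling where most genes change, and its rates need not hold there.

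Alternatives were DESeq2 size factors, library totals alone, no filter, a filter at 1 CPM, only the 6 libraries compared, a replicate block, limma-voom, the DESeq2 1.42.0 Wald test, a test against a 1.5-fold change, and leaving out each library in turn. Chosen after seeing the data were the removal of ribosomal RNA genes before scaling, leaving out 2 libraries that stand apart, and an offset per library that removes the trend with transcript length. Those 2 were replicate 3 titled ULK100, by its number of genes detected, and replicate 3 titled VPS34in1, by its ribosomal RNA. DMSO replicate 1 was kept there. Its counts differed from DMSO replicates 2 and 3 by a chi-square per degree of freedom of 7.47 and 8.51, against 2.58 between replicates 2 and 3. Equal replicate numbers did not pair libraries: the correlation of their deviations from the group mean ran from -0.0769 to 0.0403. The correlation and covariance of log2 fold changes between both comparisons with DMSO were set beside 20 simulations of unchanged groups against the same controls. No column of the table was left out. Mitochondrially encoded mRNAs were not analysed here, since 0 of the 13 fixed members are in the table.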

Results

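Gene expression was measured by RNA-seq in PANC-1 pancreatic cancer cells kept for 24 h with DMSO, with the ULK1 inhibitor ULK100 or with the VPS34 inhibitor VPS34-in1. There were 3 libraries titled DMSO, 3 titled ULK100 and 3 titled VPS34in1. The DMSO libraries held 16625690, 15985429 and 15909496 counts. The libraries titled ULK100 held 15418354, 16055523 and 14815129 counts, and those titled VPS34in1 held 14139994, 14470685 and 15277470. Titles and treatment tags of the 6 inhibitor libraries name opposite compounds, so groups are called by their titles, and no direction can be assigned to a compound without settling that conflict.

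The 3 groups separated by expression, with the first principal component holding 54.9% and the next 34.2% of the variance. Within groups the lowest correlation of log2 CPM was 0.992. Ribosomal protein genes held 8.28% to 8.93% of the counts in the libraries titled ULK100, 4.37% to 4.80% in DMSO and 4.40% to 4.90% in the libraries titled VPS34in1. Replicate 3 titled ULK100 had counts in 19326 genes, against 17282 to 17526 in the other libraries. Replicate 3 titled VPS34in1 had 4.64% of its counts in ribosomal RNA genes, against 0.774% and 0.854% in replicates 1 and 2 of that title. That share was 0.533% to 0.70% in DMSO and higher, 1.12% to 1.26%, in the libraries titled ULK100.

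**Figure D1:**
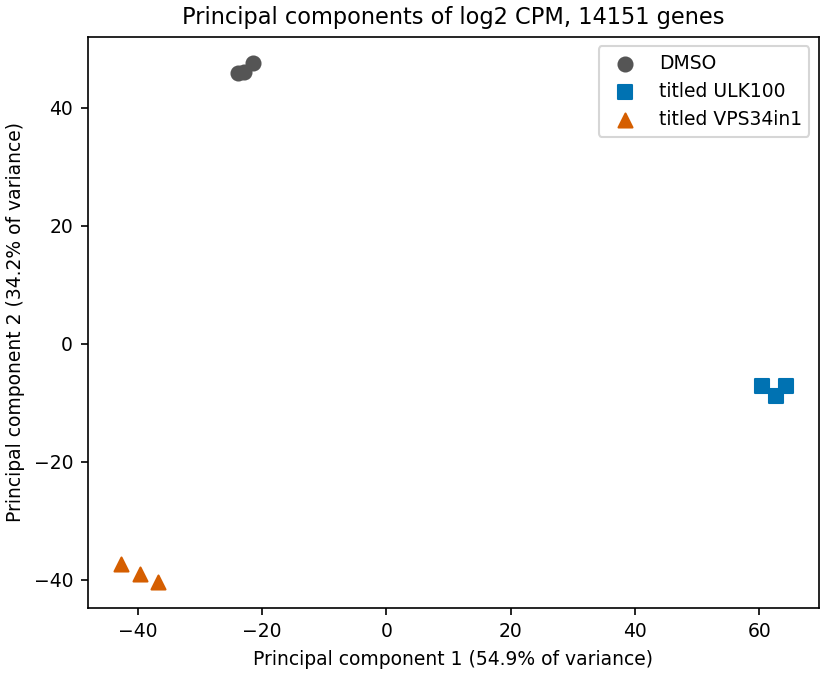
Principal components of log2 CPM over the tested genes, a point per library, coloured by title group; axes give the share of variance. The first axis (54.9%) sets the libraries titled ULK100 apart from the others, and the next (34.2%) separates all 3 groups, with DMSO and titled VPS34in1 at opposite ends.

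The comparison of libraries titled ULK100 with DMSO asked how expression differed in cells with that title from cells kept with the solvent. Stress response genes were among the largest rises. The stress transcription factor ATF3 was 39.6-fold higher (4.83 ± 0.262 CPM in DMSO, 191 ± 5.26 titled ULK100, n = 3 each), and HMOX1, which degrades heme, was 17.9-fold higher (100.4 ± 9.71 and 1800.4 ± 44.4 CPM). The collagen gene COL1A1 was 17.5-fold lower (607 ± 32.1 and 34.7 ± 1.07 CPM), and genes of DNA replication and mitosis fell together. In all, 5016 genes rose and 5130 fell of 14151 tested (71.7%). The neurotrophin receptor gene NGFR had the largest rise among named genes, 42.3-fold (2.81 ± 0.404 and 119 ± 4.16 CPM).

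Of 38 tested genes of the amino acid and integrated stress response driven by ATF4, 32 rose and 5 fell, with a median log2 fold change of 1.26 (adjusted p = 6.00e-33). ATF3 (chromosome 1, 212565334 to 212620777) changed by 5.31 (SE 0.09, adjusted p = 3.76e-30). PPP1R15A, a phosphatase subunit that ends this response, rose from 33.6 ± 0.918 to 733 ± 26.7 CPM, and the transcription factor DDIT3 rose from 33.1 ± 2.21 to 405 ± 16.2 CPM. Of 21 genes of the NRF2 and glutathione list, which counter oxidative stress, 18 rose and 2 fell, with a median of 0.96 (adjusted p = 6.90e-13). HMOX1 (chromosome 22, 35380361 to 35394214) changed by 4.16 (SE 0.08, adjusted p = 8.26e-29), and SRXN1, which repairs oxidised peroxiredoxins, changed by 2.24 (SE 0.07). Of 16 heat shock genes 10 rose and 1 fell (median 0.32, adjusted p = 8.03e-05), a call lost at adjusted p = 0.0918 with an estimated correlation. The cochaperone gene DNAJB1 rose from 203 to 676 CPM, and HSPA1A, whose near-identical copy HSPA1B may share its reads, from 574 ± 32.5 to 3514 ± 325 CPM. Of 21 p53 target genes 10 rose and 3 fell (median 0.19, or -0.0017 under library totals alone and 0.30 without DMSO replicate 2, adjusted p = 3.25e-04; adjusted p = 0.0783 with an estimated correlation), and the stress cytokine gene GDF15 among them changed by 3.19.

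Cell cycle genes fell. Of 47 genes of the G1/S transition and DNA replication 44 fell and 0 rose (median -0.97, adjusted p = 3.24e-16), among them CDC25A at -2.62 (SE 0.11), a phosphatase that activates cyclin-dependent kinases. Of 40 genes of G2/M and mitosis 39 fell and 0 rose (median -1.34, adjusted p = 1.74e-25). That call was lost at adjusted p = 0.0598 with an estimated correlation, the lowest p over the alternatives being 5.10e-33. ASPM, a spindle pole gene, changed by -3.16 (SE 0.11, adjusted p = 1.97e-22), and KIF20A, a kinesin of cytokinesis, fell from 148 ± 1.33 to 37.2 ± 5.89 CPM. Among the genes fixed by name, the proliferation marker MKI67 fell from 636 ± 111 to 165 ± 10.1 CPM, CCND1 (cyclin D1) from 285 ± 6.34 to 161 ± 7.63 CPM and E2F1 by 0.72 on the log2 scale. MYC rose from 119 ± 5.78 to 388 ± 3.23 CPM, and the cyclin-dependent kinase inhibitor genes CDKN1A and CDKN1B changed by 0.45 and 1.07. For CDKN1A the change was 0.26 under library totals alone and 0.28 with the trend over transcript length removed. Of 18 negative regulators of the cell cycle 11 rose and 7 fell (median 0.48, adjusted p = 0.0359; adjusted p = 0.0918 with an estimated correlation), with GADD45A at 3.79 and the inhibitor gene CDKN2C at -2.16. Without DMSO replicate 2 or 3 that list had adjusted p = 0.0591 and 0.0589, in a range of 0.0196 to 0.211 over the alternatives by camera.

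Autophagy genes rose. Of 36 genes of the autophagy machinery 24 rose and 5 fell (median 0.33, adjusted p = 1.08e-04), or 25 and 5 adjusted over the list alone. ULK1 (chromosome 12, 131894651 to 131923167) rose from 96.7 ± 6.87 to 260.1 ± 15.8 CPM, a log2 change of 1.43 (SE 0.07, adjusted p = 3.10e-18). MAP1LC3B, the LC3 protein of autophagosome membranes, changed by 2.23, and its relative GABARAPL1 by 1.91 (SE 0.09). PIK3C3 (chromosome 18, 41955206 to 42087830) had 6.47 ± 0.42 and 5.68 ± 0.418 CPM, a log2 difference of -0.19 (SE 0.14, adjusted p = 0.233), which was not called. It was -0.38 (adjusted p = 0.0209) when scaled by library totals alone and 0.14 (not called) with the trend over transcript length removed, a setting chosen after seeing the data, so its direction depended on the setting. Of 20 selective autophagy receptor genes 13 rose and 3 fell (median 0.58, adjusted p = 0.00583; adjusted p = 0.0618 with an estimated correlation). SQSTM1, the p62 receptor, rose from 1174 ± 49.0 to 3459 ± 99.1 CPM. Of 51 lysosomal genes 18 rose and 18 fell (median 0.02, adjusted p = 0.380), and of 36 endosome and PI3P genes 19 rose and 8 fell (median 0.21, or 0.02 under library totals alone, adjusted p = 0.167).

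Lipid synthesis genes went the other way. Of 17 fatty acid synthesis genes 13 fell and 3 rose (median -0.80, adjusted p = 3.88e-05; adjusted p = 0.0618 with an estimated correlation), and the desaturase gene SCD fell from 774 ± 30.3 to 195 ± 4.79 CPM. Of 25 genes of cholesterol synthesis and uptake 13 fell and 3 rose (median -0.25, adjusted p = 0.0156; adjusted p = 0.0618 with an estimated correlation). Of 30 hypoxia and glycolysis genes 16 rose and 6 fell (median 0.32, adjusted p = 9.02e-04; adjusted p = 0.0618 with an estimated correlation), and hexokinase HK2 changed by 3.41. Of 29 MYC and ribosome biogenesis genes 17 rose and 5 fell (median 0.36, adjusted p = 0.0163; adjusted p = 0.275 with an estimated correlation). Of 30 nuclear-encoded respiratory chain genes 21 rose and 4 fell (median 0.35, adjusted p = 0.0228; adjusted p = 0.557 with an estimated correlation). Under library totals alone that call ended too (median 0.16, adjusted p = 0.0701). Of 19 NF-kB and cytokine genes 12 rose and 4 fell (median 0.60, adjusted p = 0.0202; adjusted p = 0.0780 with an estimated correlation), and the median was 0.95 without DMSO replicate 2 and 0.91 without replicate 3 titled ULK100. Of 22 mesenchymal and TGF-beta genes 14 fell and 3 rose (median -0.50, adjusted p = 8.53e-04; adjusted p = 0.0618 with an estimated correlation), with TGFB2 at -3.00 and SPARC at -1.77. Of 5 tested fibroblast markers 4 fell and 0 rose (median -1.21, adjusted p = 3.07e-04; adjusted p = 0.0598 with an estimated correlation), led by COL1A1 (chromosome 17, 50183289 to 50201632). Without a filter on low counts the fibroblast call ended (median -0.45, adjusted p = 0.0727).

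The change also followed transcript length in the libraries titled ULK100. Across genes, which are not independent replicates, the median log2 fold change ran from 0.45 in the fifth of genes with the shortest transcripts to -0.33 in the fifth with the longest. In the comparison of titled VPS34in1 with DMSO these medians were 0.02 and -0.01. Of 82 ribosomal protein genes, a family with short transcripts that was chosen after its values were seen, 81 rose and 0 fell (median 1.12), and 79 rose under library totals alone (median 0.93). With the length trend removed their median was 0.78. In that setting the calls of the respiratory chain list (median 0.05, adjusted p = 0.273, in a range of 0.00286 to 0.557), the NF-kB list (adjusted p = 0.0758, in a range of 0.0134 to 0.078) and the negative cell cycle regulators (adjusted p = 0.0758) ended. The median of the autophagy machinery was then 0.39, of G1/S genes -0.92, of G2/M genes -1.23, of ATF4 response genes 1.33, of NRF2 genes 0.77 and of mesenchymal genes -0.27, each still called. The endosome and PI3P list was called in that setting (median 0.26, adjusted p = 0.0378, in a range of 0.0378 to 0.304).

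With an estimated correlation, the calls of the autophagy machinery (adjusted p = 0.0245), the G1/S genes (adjusted p = 0.0310), the ATF4 response (adjusted p = 0.00115) and the NRF2 list (adjusted p = 0.00274) held. The groups did not overlap for 10355 genes (73.2%), where chance gives 10%. Scaling by library totals alone moved the median log2 fold change of all genes by -0.19 and gave 3727 genes higher and 6522 lower (36.4% higher, against 49.4% with TMM), and the medians of the autophagy machinery (0.14), hypoxia (0.13), heat shock (0.13), ribosome biogenesis (0.18), negative cell cycle regulator (0.29) and cholesterol lists (-0.44) moved with it, each still called. Without the 2 libraries that stand apart, a setting chosen after seeing the data, 4944 genes rose and 4890 fell.

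**Figure D2:**
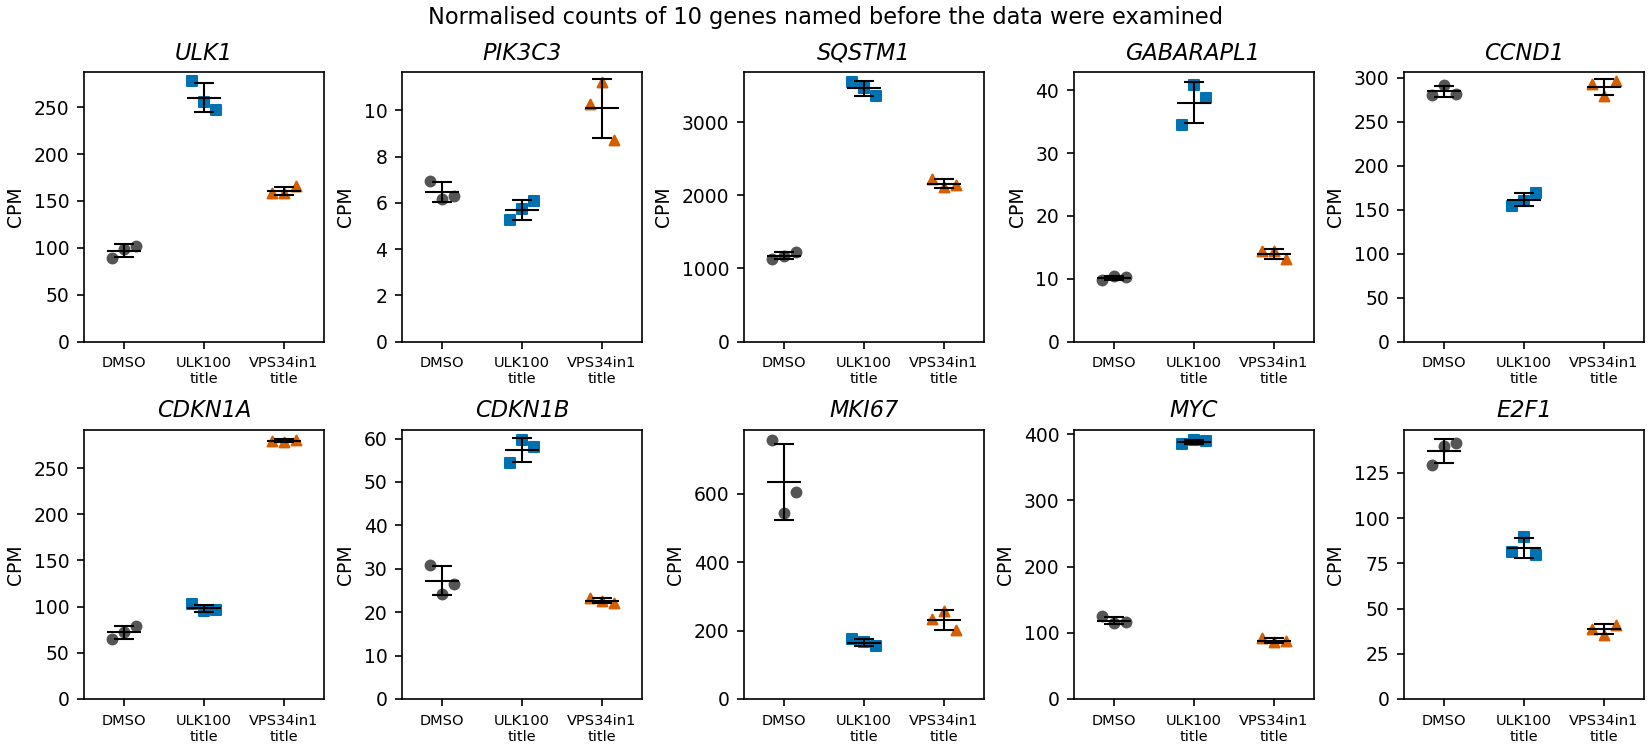
CPM of the 10 genes fixed by name in each library (points), with bars for the mean and error lines for the SD of each title group (n = 3), on axes from 0. SQSTM1, ULK1 and GABARAPL1 were higher under both titles than in DMSO, and MKI67 and E2F1 were lower.

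The comparison of libraries titled VPS34in1 with DMSO asked the same of the other inhibitor title. Genes of cholesterol synthesis and uptake rose, inflammatory genes rose, and replication and mitosis genes fell. The stanniocalcin hormone gene STC1 had the largest rise among named genes, 74.5-fold (2.54 ± 0.593 CPM in DMSO and 190.0 ± 14.7 titled VPS34in1, n = 3 each), and the matrix gene MXRA5 had the largest fall (33.5 ± 0.264 and 1.08 ± 0.257 CPM). DHCR7, an enzyme of late cholesterol synthesis, was 4.99-fold higher (243 ± 29.01 and 1210.1 ± 53.3 CPM). In all, 4557 genes rose and 4538 fell (64.3%).

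Of 25 cholesterol genes 24 rose and 1 fell (median 1.52, adjusted p = 7.27e-35). DHCR7 changed by 2.32 (SE 0.07, adjusted p = 7.86e-23), MVD of the mevalonate pathway by 2.44, and the sterol-regulated gene INSIG1 rose from 65.0 ± 2.13 to 261 ± 6.29 CPM. Of 17 fatty acid synthesis genes 9 rose and 6 fell (median 0.25, adjusted p = 0.0608). Without replicate 3 titled VPS34in1 that list was called (median 0.31, adjusted p = 0.0341, in a range of 0.0341 to 0.301 over the alternatives by camera). Of 51 lysosomal genes 42 rose and 3 fell, or 43 and 3 adjusted over the list alone (median 0.52, adjusted p = 1.96e-07). That call was lost at adjusted p = 0.132 with an estimated correlation, the lowest p over the alternatives being 1.04e-12. The protease gene CTSL changed by 1.23 and NPC2, which carries cholesterol out of lysosomes, rose from 46.6 ± 0.825 to 123 ± 5.09 CPM. Of 36 endosome and PI3P genes 17 rose and 3 fell, or 16 and 3 adjusted over the list alone (median 0.15, or 0.08 under library totals alone, adjusted p = 0.0247; adjusted p = 0.0874 with an estimated correlation).

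Of 36 autophagy machinery genes 29 rose and 0 fell, or 30 and 1 adjusted over the list alone (median 0.40, adjusted p = 1.14e-04), with the lipid transfer gene ATG2A at 1.52 and WIPI1, which binds PI3P, at 1.71. ULK1 changed by 0.73 (adjusted p = 6.73e-11), GABARAPL1 by 0.46 (adjusted p = 3.27e-04), and PIK3C3 rose from 6.47 ± 0.42 to 10.1 ± 1.26 CPM (0.64, adjusted p = 6.48e-05). Of 20 selective autophagy receptors 11 rose and 1 fell (median 0.27, adjusted p = 0.0110; adjusted p = 0.0676 with an estimated correlation), with CALCOCO1 at 1.03 and SQSTM1 at 0.88.

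Of 47 G1/S and replication genes 46 fell and 0 rose, or 47 and 0 adjusted over the list alone (median -1.23, adjusted p = 1.36e-35). RRM2, a subunit of ribonucleotide reductase, changed by -2.37 (SE 0.07, adjusted p = 1.28e-23), from 610.3 ± 23.2 to 118 ± 3.7 CPM, and the helicase gene MCM3 by -1.82. Of 40 mitosis genes 39 fell and 0 rose (median -1.56, adjusted p = 6.23e-48), with the anaphase activator CDC20 at -1.93, KIF20A at -2.44 and the kinase gene PLK1 at -1.86. MKI67 changed by -1.46, E2F1 by -1.83 and MYC by -0.43. CDKN1A rose from 71.98 ± 7.37 to 280 ± 1.27 CPM, and CCND1 had 285 ± 6.34 and 290 ± 9.5 CPM (0.02, SE 0.06, adjusted p = 0.758). CDKN1B fell by 0.27 (adjusted p = 0.00993), but without DMSO replicate 1 the value was -0.17 (adjusted p = 0.108). Of 29 MYC and ribosome biogenesis genes 25 fell and 2 rose, or 26 and 2 adjusted over the list alone (median -0.58, adjusted p = 8.15e-06; adjusted p = 0.0874 with an estimated correlation), with HEATR1 at -1.01.

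Signalling outputs changed as well. Of 19 NF-kB and cytokine genes 15 rose and 1 fell (median 1.70, adjusted p = 1.06e-11), and the adhesion gene ICAM1 rose from 293 ± 12.1 to 1140.2 ± 45.4 CPM. Of 24 ERK pathway output genes 16 rose and 2 fell (median 0.93, adjusted p = 1.25e-08), with the phosphatase gene DUSP5 at 2.89 and the growth factor gene HBEGF at 2.89. Of 30 hypoxia and glycolysis genes 21 rose and 5 fell (median 0.43, adjusted p = 3.28e-06), with NDRG1 at 3.92 (SE 0.10). Of 22 FOXO target genes 13 rose and 4 fell, or 13 and 5 adjusted over the list alone (median 0.46, adjusted p = 0.00396), with the ubiquitin ligase gene FBXO32 at 2.33. Of 21 YAP/TEAD target genes 13 fell and 3 rose (median -0.55, adjusted p = 1.78e-05). ID3, an inhibitor of differentiation (chromosome 1, 23557918 to 23559794), fell from 139 ± 5.67 to 9.55 ± 0.471 CPM. The ATF4 response list was not called (16 rose and 16 fell, or 16 and 17 adjusted over the list alone, median -0.05 with the test pointing up, adjusted p = 0.767), nor was the NRF2 list (8 rose and 5 fell, median -0.03 with the test pointing up, adjusted p = 0.767).

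The calls of the autophagy machinery (adjusted p = 0.0165), G1/S (0.00682), G2/M (0.0165), cholesterol (2.20e-04), hypoxia (0.0205), FOXO (0.0417), ERK (0.0205), NF-kB (0.00332) and YAP/TEAD lists (0.0417) held with an estimated correlation. The groups did not overlap for 9368 genes (66.2%), where chance gives 10%. Without the 2 libraries that stand apart 4366 genes rose and 4269 fell.

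**Figure D3:**
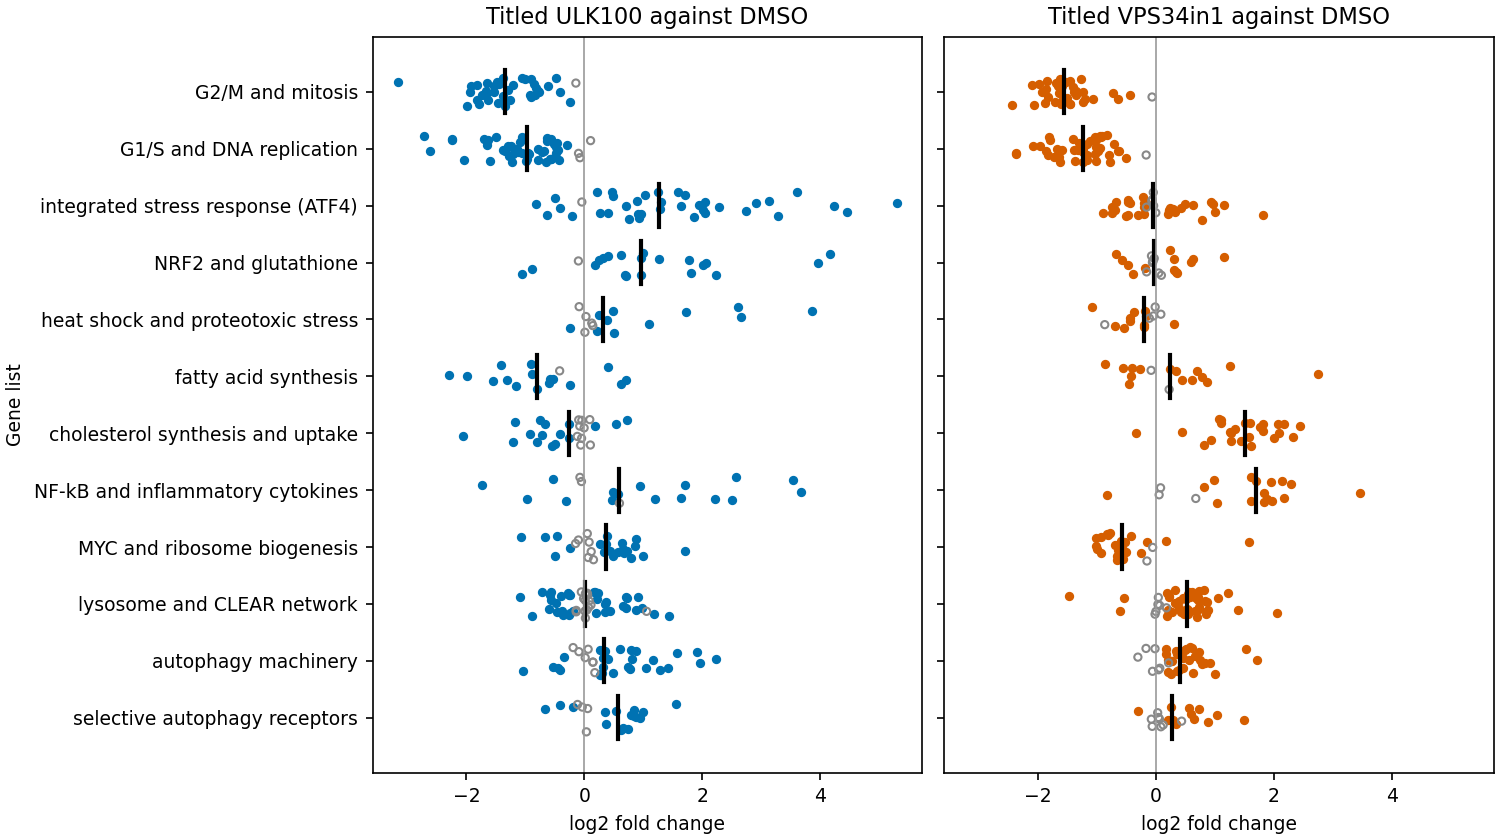
Log2 fold change against DMSO of each tested member of 12 gene lists (points, filled where adjusted p was under 0.05) under both inhibitor titles, with a black bar for each list's median. G1/S and G2/M genes lie below 0 under both titles, while the ATF4 list has a median of 1.26 titled ULK100 and the cholesterol list 1.52 titled VPS34in1.

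Both inhibitor titles shared more calls in the same direction than independent lists would. Of all tested genes 2151 rose in both comparisons with DMSO and 2442 fell in both, where independent lists of these sizes would share 1615 and 1645. Another 1047 genes rose titled ULK100 and fell titled VPS34in1, and 1158 did the reverse. GDF15 rose under both titles, from 116 ± 2.61 CPM in DMSO to 1059 ± 22.7 titled ULK100 and 1566 ± 171 titled VPS34in1. COL1A1 and MXRA5 fell under both. Both comparisons use the same 3 DMSO libraries, which gives a correlation by itself. Across genes r was 0.37, and in 20 simulations of unchanged groups it was 0.465 to 0.502. The simulated fold changes hold noise alone, so their r is no measure of how much of the observed r the controls gave. The covariance is on the same scale in both: 0.262 observed, against a simulated mean of 0.0116. Noise in the shared controls thus gave a small part of it. The 3 controls were not split between the comparisons.

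**Figure D4:**
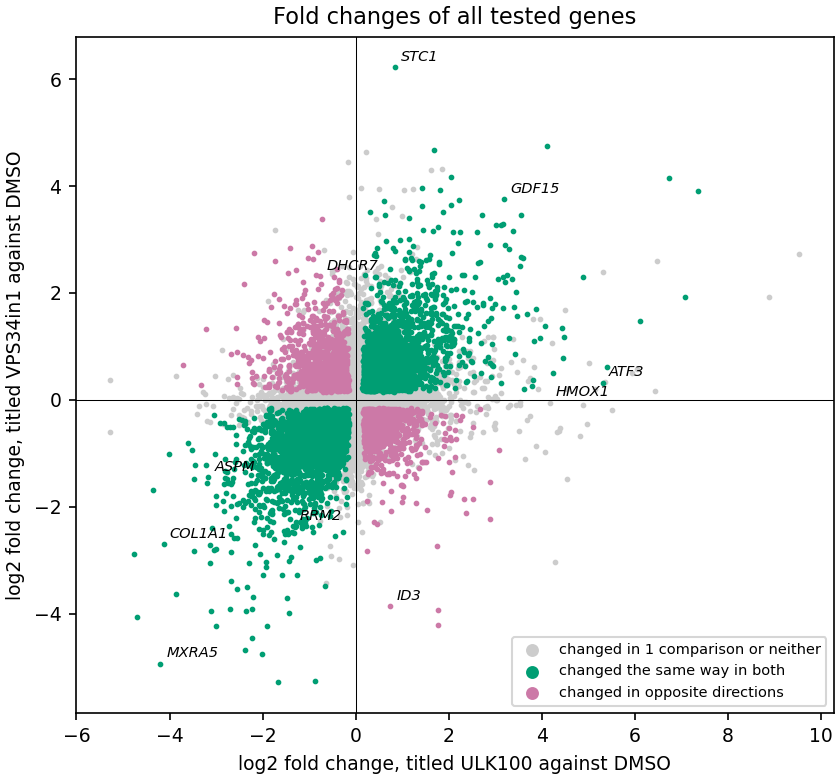
Log2 fold change of every tested gene in libraries titled ULK100 (horizontal axis) and titled VPS34in1 (vertical axis) against DMSO, coloured by whether the gene was called in both comparisons in the same or in opposite directions, with 10 genes labelled. Across genes r was 0.37.

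The direct comparison of titled VPS34in1 with titled ULK100 asked where the inhibitor titles differed. Lipid synthesis genes were higher titled VPS34in1, and stress response genes were higher titled ULK100. The hyaluronan synthase gene HAS3 had 408 ± 9.6 CPM titled VPS34in1 and 13.4 ± 1.16 titled ULK100 (60.6 ± 6.09 in DMSO), a 30.5-fold difference, and STC1 differed by 5.38 (SE 0.11, adjusted p = 4.37e-28). OASL, an interferon-induced gene, was lower titled VPS34in1 by the most among named genes (-5.71, SE 0.21). In all, 5257 genes were higher and 5117 lower titled VPS34in1 (73.3%), at doses that differ between the compounds.

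Of 25 cholesterol genes 23 were higher and 1 lower titled VPS34in1 (median 1.87, adjusted p = 5.77e-34), with DHCR7 at 3.08. Of 17 fatty acid synthesis genes 14 were higher and 2 lower (median 1.13, adjusted p = 3.12e-08), with SCD at 2.77. Of 38 ATF4 response genes 32 were lower and 3 higher (median -1.41, adjusted p = 1.37e-29), with ATF3 at -4.98 and DDIT3 at -3.41. Of 21 NRF2 genes 17 were lower and 2 higher (median -0.76, adjusted p = 8.87e-11), with HMOX1 at -4.22. Of 19 NF-kB genes 13 were higher and 4 lower (median 0.89, adjusted p = 0.00131), with ICAM1 at 2.27. Of 16 heat shock genes 14 were lower and 0 higher (median -0.83, adjusted p = 1.14e-07; adjusted p = 0.0813 with an estimated correlation). Of 29 MYC and ribosome biogenesis genes 26 were lower and 1 higher (median -0.79, adjusted p = 3.12e-09; adjusted p = 0.0676 with an estimated correlation), with MYC at -2.14 and NPM1 at -1.45. Of 30 respiratory chain genes 24 were lower and 1 higher (median -0.48, adjusted p = 1.87e-04; adjusted p = 0.387 with an estimated correlation). The median over genes again ran with transcript length, from -0.44 in the fifth with the shortest transcripts to 0.33 in the fifth with the longest. With that trend removed the respiratory chain median was -0.28 and the G1/S median -0.25, each still called.

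Of 51 lysosomal genes 36 were higher and 7 lower titled VPS34in1 (median 0.48, adjusted p = 0.00108; adjusted p = 0.387 with an estimated correlation), with LIPA, which splits cholesterol esters, at 1.07. The autophagy machinery was not called as a list: 13 genes were higher and 14 lower (adjusted p = 0.570), with MAP1LC3B at -1.57 and ATG2A at 1.20. Of 47 G1/S genes 29 were lower and 11 higher (median -0.38, adjusted p = 0.0315; adjusted p = 0.387 with an estimated correlation). Of 40 G2/M genes 21 were lower and 7 higher (median -0.19, adjusted p = 0.0670), with CDC20 at -1.32 and ASPM at 1.71. Without replicate 1 titled ULK100 or replicate 2 titled VPS34in1 the G2/M list was called (adjusted p = 0.0379 and 0.0329, in a range of 0.0147 to 0.628 over the alternatives by camera). Of 24 ERK output genes 15 were higher and 6 lower (median 0.83, adjusted p = 0.0402; adjusted p = 0.290 with an estimated correlation). Without replicate 2 titled ULK100 the ERK list had adjusted p = 0.0539, in a range of 0.00447 to 0.290.

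The calls of the ATF4 (adjusted p = 4.68e-04), cholesterol (2.29e-04), fatty acid (0.0461), NRF2 (0.00381) and NF-kB lists (0.0461) held with an estimated correlation. The groups did not overlap for 10595 genes (74.9%), where chance gives 10%. Without the 2 libraries that stand apart 4944 genes were higher and 4815 lower titled VPS34in1. Where counts of a list are given for a comparison with no others beside them, those adjusted over the list alone were the same.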

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

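Of the settings below, the removal of ribosomal RNA genes, leaving out the 2 libraries that stand apart and the removal of the length trend were chosen only after the data were seen. Among the settings run for each result, at most 20 for a list and 18 for a named gene, no test that passed in either setting pointed the other way. The sign of the median changed in at least 1 setting for 2 called lists, p53 targets titled ULK100 (0.19 to -0.0017 under library totals) and YAP/TEAD targets in the direct comparison (0.05 to -0.12 with the length trend removed), and for 13 lists that were not called. Among named genes this happened to 2 values that were not called, PIK3C3 titled ULK100 (-0.19 to 0.14) and CCND1 titled VPS34in1 (0.02 to -0.05). Counts of genes stayed within 1.5 times the reported ones, except in the test against a 1.5-fold change, which by its construction calls fewer genes: 1937 higher and 2120 lower for titled ULK100 against DMSO, 1461 and 1335 for titled VPS34in1 against DMSO, and 2344 and 2145 for titled VPS34in1 against titled ULK100. Leaving out each library in turn gave 4787 to 5150 higher and 4776 to 5191 lower, 4240 to 4598 and 4168 to 4516, and 4979 to 5375 and 4861 to 5236, in the same order. Genes higher in both comparisons with DMSO then numbered 1910 to 2141, and lower in both 2222 to 2459. With a replicate block the counts were 4966 and 5055, 4473 and 4450, and 5208 and 5040. Of the results for lists, 1457 kept their side of the threshold, 40 passed it newly (30 of them by fry, which does not compare a list with other genes) and 53 no longer passed it (30 of them with an estimated correlation). In 43 of the 48 called lists the estimated correlation gave the highest adjusted p of all settings. Of the results for named genes 4747 kept their side, 21 no longer passed and 1 passed newly, for 6 of 265 genes and comparisons.

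With an estimated correlation camera no longer called G2/M genes for titled ULK100 against DMSO (median -1.34, adjusted p = 0.0598), lysosomal genes for titled VPS34in1 against DMSO (0.52, adjusted p = 0.132) or for the direct comparison (0.48, adjusted p = 0.387), or G1/S genes for the direct comparison (-0.38, adjusted p = 0.387). The medians do not change in that setting, only the correlation assumed between genes. All 78 list results passed by fry, so a pass by fry does not set a list apart from the others. Among them were lysosomal genes for titled ULK100 against DMSO (0.020, adjusted p = 0.0455). In the direct comparison they included the autophagy machinery (-0.0043, adjusted p = 0.00191) and G2/M genes (-0.19, adjusted p = 0.00718). G2/M genes in the direct comparison also passed without a filter on low counts (-0.18, adjusted p = 0.0147). They passed without replicate 1 titled ULK100 (-0.22, adjusted p = 0.0379) and without replicate 2 titled VPS34in1 (-0.25, adjusted p = 0.0329), with medians of -0.25 to -0.18 over the libraries left out. The cause was not tested. At this depth 29 of 67 genes with the smallest simulated change were recovered, so changes of that size can be missed.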

Other observations

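All 3 tests of the extra genes in a library titled ULK100 and the test of SNHG genes against genes of equal length were chosen only after the result was seen, as were the SNHG and ribosomal protein families and the settings that remove the length trend or leave out 2 libraries.

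Further gene groups were tested against DMSO. Of 26 interferon response genes 13 rose and 7 fell titled ULK100 (median 0.21, or 0.020 under library totals alone and 0.11 with the length trend removed, adjusted p = 0.0163; adjusted p = 0.124 with an estimated correlation and 0.109 without a filter), with IFIT2 at 2.52 and ISG15 at 1.94. In the libraries titled VPS34in1 10 rose and 8 fell, or 10 and 9 adjusted over the list alone (adjusted p = 0.554), with ISG20 at 3.74 and IFIT1 at -2.32. Of 24 ERK output genes 12 rose and 8 fell titled ULK100 (median 0.24, or 0.05 under library totals alone and 0.13 without replicate 3 titled ULK100, adjusted p = 0.0151; adjusted p = 0.164 with an estimated correlation and 0.184 without a filter), with HBEGF at 3.20. Of 24 genes of the unfolded protein response 10 rose and 8 fell titled ULK100 (adjusted p = 0.229), with the chaperone gene HSPA5 at 2.15. In the libraries titled VPS34in1 14 rose and 2 fell (median 0.28, adjusted p = 0.0450; adjusted p = 0.125 with an estimated correlation), a call that also ended under library totals alone (adjusted p = 0.0637), at a filter of 1 CPM (0.0508) and without replicate 2 of that title (0.0628), in a range of 0.00221 to 0.125. Of 30 respiratory chain genes 15 fell and 1 rose titled VPS34in1 (median -0.14, or -0.22 under library totals alone, adjusted p = 0.0467; adjusted p = 0.660 with an estimated correlation). That call ended without DMSO replicate 2 (adjusted p = 0.0584), titled ULK100 replicate 3 (0.0516), titled VPS34in1 replicate 1 (0.0714) or replicate 2 (0.0769), in a range of 0.00221 to 0.660. It also ended at a filter of 1 CPM and in a fit of only the 6 libraries compared. Of 21 YAP/TEAD targets 6 rose and 13 fell titled ULK100 (adjusted p = 0.333), with CYR61 at 1.52 and AJUBA at -1.91. In the direct comparison the YAP/TEAD list had a median of 0.05, which ran from -0.12 to 0.16 over the alternatives and was -0.0094 and -0.0033 without replicates 1 and 2 titled VPS34in1, 0.016 and 0.0085 without replicates 2 and 3 titled ULK100 and 0.11 without replicate 3 titled VPS34in1. Its mean was -0.55 and the test pointed down (adjusted p = 0.0282; adjusted p = 0.282 with an estimated correlation and 0.555 without a filter), with CTGF at -3.21. Of 21 p53 targets 11 rose and 2 fell titled VPS34in1 (median 0.23, or 0.15 under library totals alone, adjusted p = 5.67e-04; adjusted p = 0.0961 with an estimated correlation). In the direct comparison of the titles the interferon (adjusted p = 0.152), unfolded protein response (0.570) and p53 lists (0.570) were not called.

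Several lists were not called. These were FOXO targets titled ULK100 (9 rose and 7 fell, median 0.07 and mean -0.01, adjusted p = 0.616), ductal genes (7 and 8 titled ULK100, median 0.06 with the test pointing down, adjusted p = 0.296; 7 and 9 titled VPS34in1, or 7 and 10 adjusted over the list alone, median -0.18 with the test pointing up, adjusted p = 0.767), and, titled VPS34in1, the negative cell cycle regulators (7 and 7, adjusted p = 0.767), mesenchymal genes (5 and 11, adjusted p = 0.142) and heat shock genes (1 and 10, adjusted p = 0.0797). Of 5 tested endothelial markers 3 rose and 1 fell titled ULK100 (adjusted p = 0.565) and 4 rose and 0 fell titled VPS34in1 (adjusted p = 0.0938), with the highest, ESAM, at 4.11 CPM in DMSO, 4.71 titled ULK100 and 10.6 titled VPS34in1. Of 5 tested fibroblast markers 3 fell and 0 rose titled VPS34in1 (median -0.57, adjusted p = 0.00294; adjusted p = 0.0874 with an estimated correlation; -0.20 and 0.0877 without a filter), and DMSO libraries held 4 of the 12 fixed markers above 1 CPM, COL1A1 at 645 CPM. CPM of other-cell markers are on library totals. Leukocyte markers had 4 tested members, led by CD68, a lysosomal protein gene, at 334 CPM in DMSO, 662 titled ULK100 and 563 titled VPS34in1. The acinar and islet list had 1 tested member, PDX1, at 7.13, 2.82 and 4.63 CPM, and the highest hepatocyte marker was at 0.471, 0.854 and 1.55 CPM.

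Short transcripts were higher and long ones lower in the libraries titled ULK100, with a Spearman correlation across genes of -0.346 between log2 fold change and transcript length, against -0.0156 titled VPS34in1. Length bias of fragmentation or library preparation alone stays open. At a fixed transcript length the correlation with the gene's span on the genome was -0.0671 (95% bootstrap interval -0.0839 to -0.0513). That lies narrowly past the bound of -0.05, on the side against length bias alone. Lengths are those of each gene's longest annotated transcript, so a remainder this small can arise where shorter forms were expressed. A few abundant short genes alone were argued against, since the correlation with transcript length was -0.336 (-0.352 to -0.321) without ribosomal protein genes and the 500 most abundant genes. Less RNA made from genes with a long span stays open, as a biological candidate explanation of the title group: at middle transcript lengths the longest spans lay lower than the shortest by a median difference of -0.166 (-0.286 to -0.0768), an interval that crosses the bound of -0.1.

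Replicate 3 titled ULK100 held 1292 genes that no other library showed, with 2244 counts and at most 9 per gene. Deeper sequencing was argued against, since its total was 0.946 of the median of the others. RNA of another human cell type stays open: the 10 genes with the most counts held 3.48% of the extra counts, but with at most 9 counts per gene they could hold no more than 4.01%, so that share decides nothing. Reads spread evenly over the genome, such as genomic DNA, stay open as well. Over 5328 genes at 0 in the other 8 libraries its count rose with transcript length (Spearman 0.371, 0.349 to 0.392). With randomly primed cDNA longer RNAs can also give more reads, so this rise does not separate genomic DNA from RNA. No biological explanation was tested.

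Host genes of small nucleolar RNAs, taken as the 18 tested genes named SNHG, were mostly higher titled ULK100: 11 rose and 1 fell (SNHG4, -1.13), with a median of 1.22, and 11 rose and 4 fell under library totals alone. Whether short transcripts alone account for this stays open. Sets of other genes of near-equal annotated length had a lower median of 0.30 (central 95% of 10000 sets -0.11 to 0.67). That comparison cannot decide the question, because the family was chosen after its values were seen. A median above those of drawn sets was thus likely beforehand. With the length trend removed 10 of the 11 were still called higher and 4 genes were lower. Their median was then 1.02, and its bootstrap interval (0.0464 to 1.33) reached below the bound of 0.2 set beforehand. That test left short transcripts undecided as well. Both tests took each gene's longest annotated transcript (median 2247.5 nt for SNHG genes), so an effect of shorter expressed forms stays open. Less nonsense-mediated decay, which degrades these RNAs, may contribute, a hypothesis: 5 of 7 decay factor genes that are themselves kept low by it were called higher with the length trend removed, among them UPF3B at 1.00 and UPF2 at 0.82. That test is weak, because 3 of 7 were called higher without the correction and 35.5% of all genes were called higher with it. In the libraries titled VPS34in1 3 SNHG genes rose and 10 fell (median -0.50).

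The 6 libraries of each comparison were also split in every other way and tested with edgeR. In each comparison 1 of the 10 splits, the real one, gave as many genes: 10113 for titled ULK100 against DMSO, 8886 for titled VPS34in1 against DMSO and 10288 for the direct comparison, with 0 as the highest of the others. With 10 splits a share under 0.05 cannot be reached. Each of the other splits mixes libraries of both groups, which widens the spread within its parts, so low counts were likely there beforehand.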
